A study of Homo sapiens with 12 samples.

How the data were processed

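RNA was measured in 12 libraries of HCT116 cells expressing Cas9, 4 with no reporter, 4 with the L1 WT reporter and 4 with the L1 EN/RT mutant reporter, grouped by the titles and labels of the samples. Per the submitters' processing notes, the authors used STAR 2.7.11, SAMtools 1.21, Salmon 1.10.2 and DESeq2 1.30.1 with the human build GRCh38. The role of each tool, the annotation used and whether counting used strand are not given in the sources used here. The deposited tables give for each gene a read count, which is a whole number and not normalized, and the authors' TPM value, which is scaled for gene length and to a fixed total per library.

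Each table used here listed a different part of the genes. Together they held 39122 identifiers, of which 38974 matched the names table or annotation and 15612 had a read in at least 1 library. A gene not listed in a library was treated as missing and not as 0. For 229 genes a count was listed with an empty TPM cell; these entered the count test and could not meet a rule on TPM. Because a sum over part of a library is not its depth, relative depth was taken from the ratio of count to TPM over 7892 genes, which is the same for every library up to its depth, and was then multiplied by a TMM factor computed on the 286 to 364 genes that a library shared with L1 WT replicate 2.

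The planned test was edgeR's quasi-likelihood test over genes listed in every library. It could not be run as planned, since 0 expressed genes were listed in all 12 libraries or in all 8 libraries of a comparison, and an expressed gene was listed in at most 8. In its place the edgeR model (R 4.3.3, edgeR 4.0.16, limma 3.58.1) was fitted to each gene over the libraries that listed it, with 1 common dispersion of 0.00211 (a biological coefficient of variation of 4.59%), robust quasi-likelihood moderation with a prior of 9.94 degrees of freedom, and all 3 groups in one fit. Genes needed a mean normalised count of at least 10, which kept 11085, of which 3572 had residual degrees of freedom. The adapted design was chosen after the listing was seen and on simulated counts, without regard to the genes it called. P-values were two-sided and adjusted by Benjamini and Hochberg, with a threshold of 0.05. Standard errors are the log2 fold change divided by the signed root of the F statistic.

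The procedure was tested on simulated counts with 200 changed genes. For L1 WT against no reporter it recovered 87% of genes changed 1.5-fold and 94% of those changed 2-fold, with 4.74% false among 190 calls, and it made 2 calls when nothing was changed. For the mutant against no reporter the values were 83% and 92%, with 5.91% false, and for L1 WT against the mutant 88% and 97%, with 5.61% false. The simulation gave all groups the same spread. Between the real mutant libraries the median difference was 1.39 times that of controls, over genes with at least 500 reads. The shares of false calls may therefore not hold for comparisons with the mutant. On a complete simulated matrix of 2999 genes its -log10 p-values had a Pearson correlation of 0.99994 with those of edgeR's own function.

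The 28 gene lists were fixed before the data were examined. A list with at least 5 tested members was tested with camera at an inter-gene correlation of 0.01, and again with a correlation of 0.143 estimated from 7 pairs of values. So few pairs give no firm estimate, so the second p-value is only a weak check on the first. For lists with at least 3 members listed in both groups, an effect per library was tested by exact permutation over 70 relabelings, a choice made after the data were seen. The fry test needs complete data and was not run. The rule for named genes, also fixed before the data were examined, took up to 12 genes per direction with the largest fold change among those past the threshold with a mean of at least 5 TPM and no overlap between the groups, up to 4 members of a list that passed, and a set of fixed genes; a few genes that the rule names are not reported here. With few libraries per gene, groups often fail to overlap by chance. Coordinates and exon overlap came from GENCODE release 29 on GRCh38. Of the 50 genes the rule named, 3 shared at least 10% of their exonic bases with another gene, DDIT4 (41.2%), GOT1 (19.3%) and MRC2 (12.6%), all on the opposite strand.

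Alternatives covered DESeq2 1.42.0, other size factors, filters, thinning to the shallowest library, a replicate block, leaving out each library and other readings of unlisted genes. Figures were drawn with matplotlib 3.10.9.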

Results

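Polyadenylated RNA was sequenced from HCT116 cells that stably expressed the Cas9 nuclease. HCT116 is an established human colorectal carcinoma line. The 12 libraries formed 3 groups of 4 replicates: cells with no reporter (controls), cells with a dual reporter built on a wild-type LINE-1 retrotransposon (L1 WT), and cells with the same kind of reporter mutated in the L1 endonuclease and reverse transcriptase (L1 EN/RT mutant). The labels describe hygromycin at 100 µg/mL for the reporter cells and do not say whether the controls received it, so that a difference between reporter cells and controls could not be separated from a possible difference in selection. The labels did not say whether replicates came from separate cultures, so the spread between these samples, on which the p-values below rest, may be technical. At least 2 libraries in both groups listed 171 of 1387 genes tested in L1 WT against controls, and 159 of 1359 in the mutant. Between the reporter lines these were 164 of 1384. With so few libraries per gene, most of the spread used for a gene came from the prior shared over genes.

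The tables used here listed a different subset of genes in each library. Mutant replicates 2, 3 and 4 listed 5454, 4169 and 3917 rows, against 12074 to 12615 in the other 9 libraries. They held between 1641 and 2933 rows at 0 reads, against 9651 to 10280 in the others, so that few genes without reads can be seen in them. Reads summed over the listed genes ran from 4222016 in L1 WT replicate 4 to 7448261 in mutant replicate 2, and between 2276 and 2521 genes per library had reads. Relative depth, estimated from genes listed with both a count and a TPM value, ran from 0.877 in L1 WT replicate 2 to 1.32 in mutant replicate 2. Mean relative depth was 0.919 ± 0.0351 (SD, n = 4) in L1 WT, 1.13 ± 0.187 in the mutant and 0.975 ± 0.108 in controls. The L1 WT libraries were shallower than the mutant libraries in an exact two-sided permutation test (p = 0.0286, the smallest that 70 relabelings allow; adjusted p = 0.0857 over 12 tests of library measures). The number of rows listed gave the same p-values in each of the 3 comparisons. No expressed gene was listed in all 12 libraries, and the median expressed gene was listed in 2, so values below rest on few libraries. The number of libraries is given beside TPM values, and a value with n = 1 has no SD. A gene with 1 library in each of the compared groups takes its spread from the libraries of the remaining group and from the shared prior of the fit.

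Genes chosen in advance gave the background levels of the line. The epithelial marker EPCAM was at 447 TPM in control replicate 4 and 398 TPM in L1 WT replicate 3, and the keratin gene KRT18 was at 526 TPM in mutant replicate 2. The mesenchymal filament gene VIM was at 6.08 TPM in L1 WT replicate 2 and 3.65 TPM in mutant replicate 1. The cell cycle inhibitor gene CDKN1A was at 220 TPM in control replicate 2 and 230 TPM in L1 WT replicate 1, and MDM2 was at 36.6 TPM in L1 WT replicate 3 and 35.1 TPM in mutant replicate 1. The reference genes were listed in a single library each, ACTB at 2873 TPM in L1 WT replicate 1 and GAPDH at 5123 TPM in mutant replicate 2. Among genes that act on LINE-1, MPHOSPH8 was at 34.8 TPM in control replicate 1 and 35.7 TPM in mutant replicate 4, SETDB1 had 1191 reads in L1 WT replicate 3, and L1TD1 had 0 reads in control replicate 1. TASOR, a HUSH complex subunit, was at 23.9 ± 1.12 TPM (SD, n = 2) in L1 WT and 22.7 ± 0.764 TPM (n = 3) in controls, a log2 fold change of 0.04 (SE 0.0463, edgeR adjusted p = 0.776). The innate response gene IFIT1 was at 3.48 and 4.15 TPM in control replicates 3 and 4. ISG15, TBP and MORC2 were not listed in the tables used here. The reporter sequence of the wild-type construct was listed with 0 reads in all 4 controls and in mutant replicate 1. No L1 WT library listed it, so its expression in the L1 WT cells is not shown here.

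The first comparison asked which transcripts differed between cells with the wild-type L1 reporter and cells without a reporter. Of 1387 genes tested, 18 were higher and 19 were lower in the reporter cells (edgeR quasi-likelihood test, Benjamini-Hochberg threshold of 0.05). VSNL1, which encodes a neuronal calcium sensor, rose from 12.8 ± 0.595 TPM (SD, n = 3) to 24.0 ± 2.54 TPM (n = 2), a log2 fold change of 0.89 (SE 0.083, edgeR adjusted p = 5.89e-05). The collagen receptor gene MRC2 rose from 7.94 TPM (n = 1) to 15.0 ± 1.89 TPM (n = 3), a log2 fold change of 0.86 (SE 0.12, adjusted p = 0.00606 by edgeR). The cadherin gene CDH1, the main adhesion molecule of epithelial cells, fell from 29.1 ± 1.36 TPM (n = 2) to 21.4 TPM (n = 1), a log2 fold change of -0.46 (SE 0.078). On GRCh38, VSNL1 (ENSG00000163032) lies on chromosome 2 from 17539126 to 17657018, MRC2 (ENSG00000011028) on chromosome 17 from 62627401 to 62693597 and CDH1 (ENSG00000039068) on chromosome 16 from 68737225 to 68835548, all protein-coding genes on the plus strand. The glutamate transporter gene SLC1A3 fell from 8.33 TPM (n = 1) to 4.63 ± 0.589 TPM (n = 3), a log2 fold change of -0.89 (SE 0.142).

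The transcription factor genes FOXC1 and ETV1 were among those that rose. Both, like TESC below, were listed in L1 WT by replicate 1 alone. FOXC1 went from 42.6 ± 0.394 TPM (SD, n = 2) to 65.8 TPM (n = 1), a log2 fold change of 0.58. The ETS factor gene ETV1 went from 23.2 to 36.0 TPM with 1 library in each group, a log2 fold change of 0.61. The spread used for ETV1 came from 2 mutant libraries and, for the most part, from the shared prior. TESC (0.71), the plasminogen activator gene PLAT (0.67), the phospholipase gene PLD1 (0.51), the laminin chain gene LAMA5 (0.49) and the cytokine receptor gene LIFR (0.40) had log2 fold changes in the same direction. Increases below 0.40 on this scale were found for the RNA helicase-like gene ZNFX1 (0.37), the phosphate transporter gene SLC20A1 (0.35) and the efflux pump gene ABCC2 (0.34). The chemokine gene CXCL8 rose by a log2 fold change of 1.35 (SE 0.326, edgeR adjusted p = 0.0445), from 0.953 ± 0.0993 TPM (n = 3) to 2.55 TPM in a single L1 WT library with 66 reads. Other analysis settings took CXCL8 below the threshold 8 times, ATAD3B 6 times and PLD1, LIFR and LAMA5 5 times each. The caveolin gene CAV2 fell from 172 ± 2.95 TPM (n = 2) to 132 ± 5.64 TPM (n = 2), a log2 fold change of -0.46 (SE 0.0444, adjusted p = 0.000147 by edgeR). TC2N (-0.59), the mitochondrial genes ATAD3B (-0.40) and TIMM44 (-0.34), the neuropeptide gene GAL (-0.39) and the nucleotide synthesis gene PRPS2 (-0.31) had negative log2 fold changes.

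The integrated stress response, a program that limits translation and induces amino acid metabolism genes, was the only one of the 28 fixed lists with at least 5 tested members. Of its 5 tested members 3 fell, none rose, and 4 fell when adjusted over the list alone (camera p = 1.55e-07 with a preset correlation, and p = 1.89e-05 with an estimated correlation). DDIT4, a stress-induced inhibitor of mTORC1, fell from 265 ± 7.74 TPM (SD, n = 2) to 176 TPM (n = 1), a log2 fold change of -0.70 (SE 0.0642, edgeR adjusted p = 0.000147). CHAC1, which degrades glutathione, fell from 42.2 ± 0.48 TPM (n = 2) to 26.0 TPM (n = 1), a log2 fold change of -0.74 (SE 0.0935). The alanine transaminase gene GPT2 fell from 37.7 TPM (n = 1) to 29.4 ± 0.316 TPM (n = 2), a log2 fold change of -0.40 (SE 0.0679). VEGFA had a log2 fold change of -0.30 (edgeR adjusted p = 0.0786) and ATF5 of -0.05. Averaged per library over 10 members listed in both groups, the list was lower by a log2 effect of -0.44 (exact two-sided permutation p = 0.0286, the smallest the design allows; adjusted p = 0.15 over 21 lists). DDIT4 (ENSG00000168209, chromosome 10 from 72273920 to 72276036, plus strand) shares 41.2% of its exonic bases with genes on the opposite strand, and the use of strand in counting is not given in the sources used here.

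Other fixed lists had between 0 and 4 tested members in this comparison. Among 2 tested G1/S genes the replication helicase gene MCM3 fell, with a log2 fold change of -0.25 (SE 0.0503, edgeR adjusted p = 0.0205). The 3 tested ribosomal protein genes and the 4 tested heat shock genes did not pass the threshold over all genes. Of 2 tested interferon-stimulated genes, HERC6 had a log2 fold change of 0.28 and BST2 of 0.40, and neither passed.

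The number of genes called depended on single libraries and on how the values were fitted. Without control replicate 2 the count was 7, without control replicate 3 it was 13, without L1 WT replicate 4 it was 14, without control replicate 1 it was 21 and without L1 WT replicate 3 it was 23; a fit to the 8 compared libraries gave 80, and depth taken from TPM alone gave 68, of which 49 were higher and 19 lower.

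The second comparison asked the same of cells with the L1 EN/RT mutant reporter. Of 1359 genes tested, 24 were higher and 25 were lower than in controls by the same edgeR test and threshold. MRC2 rose from 7.94 to 13.0 TPM with 1 library in each group, a log2 fold change of 0.71 (SE 0.14). The spread used for MRC2 came from 3 L1 WT libraries and, for the most part, from the shared prior. The synaptotagmin-like gene SYTL2 rose from 4.92 ± 0.082 TPM (SD, n = 2) to 7.88 ± 0.0855 TPM (n = 2), a log2 fold change of 0.64 (SE 0.0923, adjusted p = 0.00244 by edgeR). NT5E, which encodes the ectonucleotidase CD73, fell from 82.0 ± 1.17 TPM (n = 3) to 56.6 TPM (n = 1), a log2 fold change of -0.58 (SE 0.0571, edgeR adjusted p = 0.000432). CDH1 fell from 29.1 ± 1.36 TPM (n = 2) to 20.5 TPM (n = 1), a log2 fold change of -0.56 (SE 0.0781).

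The WNT receptor gene FZD1 (0.63), RAB3B (0.54), ABCC2 (0.47), VSNL1 (0.43), the kinase gene NUAK1 (0.42), the histone methyltransferase gene KMT2D (0.39), ZNFX1 (0.30), FRAS1 (0.29) and SLC20A1 (0.28) had positive log2 fold changes past the threshold. FAM107B fell from 45.0 ± 1.82 TPM (SD, n = 2) to 29.6 TPM (n = 1), a log2 fold change of -0.63 (SE 0.0689). The insulin receptor gene INSR (-0.38), the aspartate transaminase gene GOT1 (-0.37), HAX1 (-0.34), the adenosine kinase gene ADK (-0.34), FXYD5 (-0.34) and GPAT3 (-0.33) fell by less, and FXYD5 was below the threshold in 9 other settings. CXCL8 was at 1.14 ± 0.335 TPM (n = 2) against 0.953 ± 0.0993 TPM (n = 3), a log2 fold change of 0.23 (edgeR adjusted p = 0.756).

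Of 5 tested integrated stress response genes 3 fell and none rose, and 4 fell when adjusted over the list alone (camera p = 4.6e-06 with a preset correlation, and p = 0.000188 with an estimated correlation). DDIT4 fell from 265 ± 7.74 TPM (SD, n = 2) to 181 TPM (n = 1), a log2 fold change of -0.59 (SE 0.0637). CHAC1 fell from 42.2 ± 0.48 TPM (n = 2) to 30.5 TPM (n = 1), a log2 fold change of -0.51 (SE 0.0887). VEGFA fell by a log2 fold change of -0.31 (edgeR adjusted p = 0.0494), a call that was lost in 12 other settings, including DESeq2 (adjusted p = 0.163), and GPT2 had a value of -0.22 (adjusted p = 0.162 by edgeR). The effect per library over 9 members was -0.40 (exact two-sided permutation p = 0.0857; adjusted p = 0.204 over 19 lists). Of 4 tested cytosolic ribosomal protein genes 2 fell, RPL11 with a log2 fold change of -0.34 and RPL3, with 1 library in each group, with -0.31, and both have processed pseudogenes with which reads can be shared. The mitochondrial chaperone gene HSPD1 fell by a log2 fold change of -0.20, the only one of 3 tested heat shock genes to pass.

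Without control replicate 2 the count of genes was 14, without control replicate 3 it was 15 and without control replicate 1 it was 23; a fit to the 8 compared libraries gave 30. Depth taken from TPM alone gave 59, of which 39 were higher and 20 lower.

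The third comparison set the reporter lines against each other. The element and any other difference between the lines go together here, and no value separates them. Of 1384 genes tested, 5 were higher and 10 were lower in L1 WT by the edgeR test. JCHAIN, the joining chain of secreted antibodies, was at 6.78 TPM in L1 WT (n = 1) and 24.0 ± 2.68 TPM in the mutant (SD, n = 3), a log2 fold change of -1.83 (SE 0.172, edgeR adjusted p = 0.000168). VSNL1 was higher in L1 WT, at 24.0 ± 2.54 TPM (n = 2) against 17.8 ± 1.2 TPM (n = 2), a log2 fold change of 0.45 (SE 0.0882, adjusted p = 0.0198 by edgeR). SYTL2 was lower in L1 WT, at 4.94 TPM (n = 1) against 7.88 ± 0.0855 TPM (n = 2), a log2 fold change of -0.64 (SE 0.118). DCBLD2 was at 535 ± 41.8 TPM (n = 2) against 441 ± 2.54 TPM (n = 2), a log2 fold change of 0.24.

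STN1 (0.42), which acts at telomeres, ETV1 (0.41) and the endothelin-converting enzyme gene ECE1 (0.26) were also higher in L1 WT on the log2 scale. The circadian output factor gene TEF (-0.59), the epithelial transcription factor gene GRHL2 (-0.50) and the circadian repressor gene BHLHE40 (-0.37) were lower. In other settings several of these calls were lost, ECE1 in 9, ETV1 in 8, VSNL1 and TEF in 7 each, BHLHE40 in 5, and STN1, SYTL2 and DCBLD2 in 4 each. None of 7 tested integrated stress response genes passed the threshold (camera p = 0.745, and p = 0.805 with an estimated correlation), and their effect per library was -0.05 (exact two-sided permutation p = 0.857).

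DESeq2 called 8 genes here and depth taken from TPM alone called 24, of which 12 were higher and 12 lower. Without L1 WT replicate 3 the count was 5, without L1 WT replicate 4 it was 6, and it was 9 without L1 WT replicate 1, mutant replicate 1 or mutant replicate 3.

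Both reporter lines were then compared for changes they had in common. Of 801 genes tested against controls in both, 9 passed the threshold in both in the same direction and 0 in opposite directions. MRC2, VSNL1, ABCC2, ZNFX1 and SLC20A1 were higher in both lines, and DDIT4, CHAC1, CDH1 and PRPS2 were lower. A single control library served both comparisons for MRC2 and PRPS2 (control replicate 2) and for ZNFX1 (control replicate 3). For these, 1 unusual control value could give a change in both lines. Independent lists of these sizes, 23 and 25 calls, would share 0.195 higher and 0.165 lower genes. Unchanged groups simulated 20 times against the same controls shared 0.05 on average. These simulations gave all groups the same spread and held no changed genes, so they had few calls to share. The lists of 23 and 25 calls rest on the same controls and are not independent. Neither number therefore shows how many of these calls the shared controls alone would bring together. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.412 and a Spearman correlation of 0.546, against simulated means of 0.5 and 0.461. The highest simulated Pearson correlation was 0.608. Over genes with a mean of at least 5 TPM the observed one was 0.663 (simulated mean 0.507, highest 0.580) and without the 10 genes beyond 2 log2 units it was 0.599 (simulated mean 0.501, highest 0.608). It was 0.222 without control replicate 1, 0.235 without L1 WT replicate 2 and 0.232 without mutant replicate 3 (simulated means 0.516, 0.486 and 0.477, lowest 0.371, 0.354 and 0.300). The covariance was 0.0694 against a simulated mean of 0.0164 and a highest simulated value of 0.0204. Without the 10 genes beyond 2 log2 units it was 0.0397 (highest simulated 0.0204), so these few genes carried much of the value. It was 0.0163 over genes with a mean of at least 5 TPM (highest simulated 0.00731), and 0.0284 without control replicate 1, 0.0267 without L1 WT replicate 2, 0.0440 without mutant replicate 2 and 0.0279 without mutant replicate 3 (highest simulated 0.0211, 0.0202, 0.0193 and 0.0181). Over every gene with at least 1 count it was 0.228, by DESeq2 0.0249 and in fits to only the 8 compared libraries 0.0287. No simulated values were made for these settings. With the controls split so that each line had its own 2, the covariance lay between -0.0240 and 0.00582, and between 0 and 1 genes were shared, where 119 to 136 genes could be tested with 1 to 5 calls per line. Without control replicate 2 the count of shared genes was 2, without control replicates 1 or 3 it was 4 and without L1 WT replicate 4 it was 5. Without control replicate 1 the shared genes were 4 higher and 0 lower, and without control replicate 2 they were 0 higher and 2 lower.

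**Figure D1:**
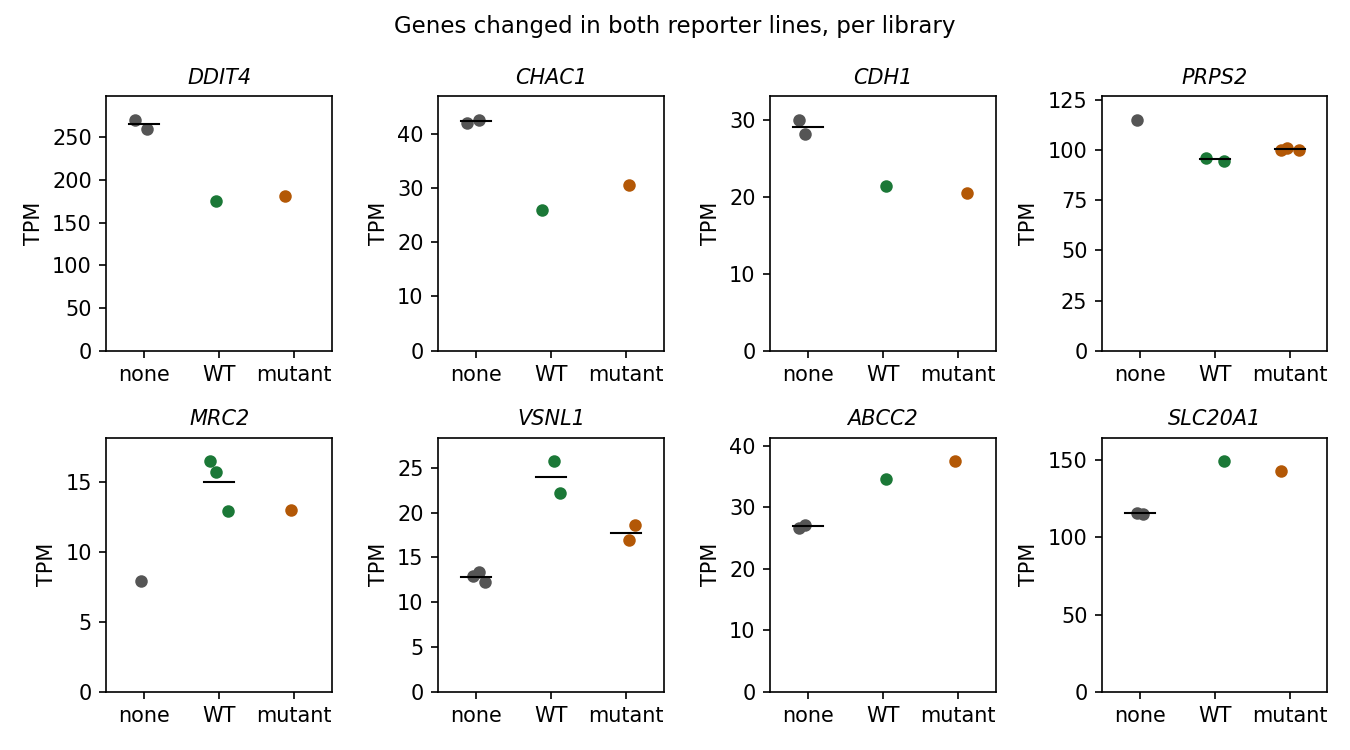
TPM per library (points, y axis) of 8 genes changed in both reporter lines, by group (x axis: no reporter, L1 WT, L1 EN/RT mutant), with a black line at the mean where 2 or more libraries listed the gene. DDIT4 was at 265 TPM on average in controls, 176 TPM in L1 WT and 181 TPM in the mutant.

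**Figure D2:**
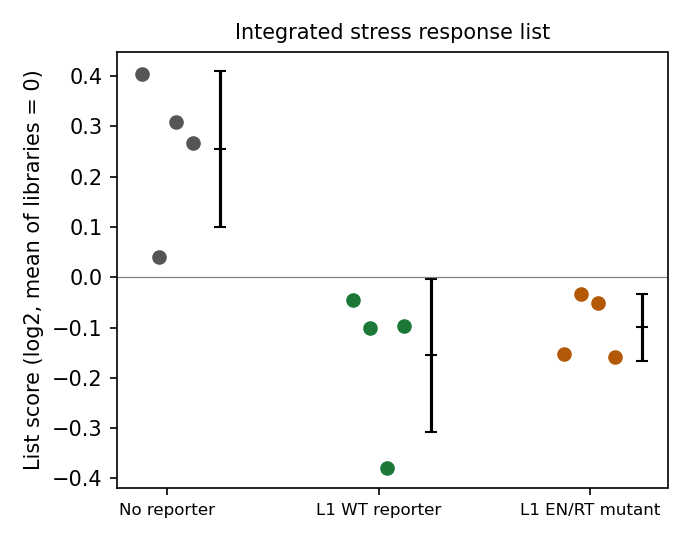
Score of the integrated stress response list per library (points, log2, y axis) in the 3 groups (x axis), with the mean and SD over 4 libraries beside the points. Control scores lay between 0.04 and 0.40, and the scores of the 8 reporter libraries between -0.38 and -0.03.

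**Figure D3:**
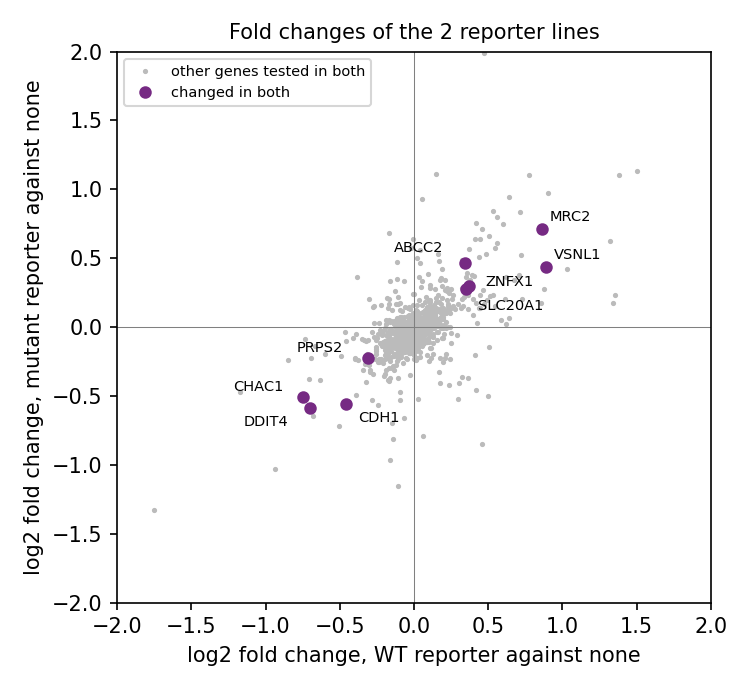
Log2 fold change against controls in the L1 WT line (x axis) and in the L1 EN/RT mutant line (y axis) for genes tested in both, within 2 log2 units on each axis, 791 of the 801; 10 lie outside the axes. Purple points are the 9 genes past the threshold in both lines, all with the same sign in both.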

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

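The splits of the samples, and the tests of the stress response and lymphoid-type patterns, were chosen only after the results were seen; the test of the spread between mutant libraries was set out before its result, and the interval given with it was added afterwards.

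In L1 WT against no reporter the real grouping called 37 genes and the highest of the other splits 12; in the mutant against no reporter the values were 49 and 21; in L1 WT against the mutant they were 15 and 5. In each comparison 1 of 35 splits, the real one, called as many genes, which is the strongest result that 35 splits allow. It argues against a chance division of the libraries as the source of these counts but cannot exclude it. The splits do not separate the reporter from any other difference between the groups.

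Of 5 tested integrated stress response genes, 3 were lower past the threshold in each reporter line, against the same controls. The list's effect per library did not pass after adjustment over the lists (exact permutation, adjusted p = 0.15 in L1 WT and 0.204 in the mutant). Without TMM factors the effect per library closer to 0 of the 2 comparisons was still -0.37. TMM factors averaged 1.02 in L1 WT, 1.00 in the mutant and 0.982 in controls. Leaving them out could therefore move the effect only a little, so this does not decide on library composition. The weakest effect after leaving out any control library was -0.34, in the mutant without control replicate 1 (exact permutation p = 0.114). For the effect over the list, this argues against a single control library. It does not cover the gene calls. Among controls, DDIT4 and CHAC1 were listed in replicates 1 and 3 alone, and GPT2 in replicate 1 alone. L1 WT replicate 3 stood apart from the other L1 WT libraries, with a list score of -0.38. The WT and mutant lines differed by -0.0526 with a permutation interval from -2.15 to 0.4, so an effect of L1 enzyme activity and none cannot be told apart with these few listed values. The labels give hygromycin for the reporter cells and do not say whether the controls received it; selection and culture state stay open, as untested.

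Some genes that were higher in the mutant line are best known from lymphoid cells. Such genes were not confined to that line. The lymphocyte integrin gene ITGB7 had a log2 fold change of 1.28 in L1 WT against controls, from 1 L1 WT library. The T cell gene CD8A was at 0.954 and 1.38 TPM in control replicates 2 and 4. The genes below are those higher in the mutant. These genes were picked out after their values were seen, and of the fixed list of immune cell markers 0 members could be tested in the mutant. PRKCQ, WIPF1, SASH3, PTPN7 and RASGRP3 passed the threshold against controls, and JCHAIN, CD74 and WIPF1 (-3.31, log2, L1 WT minus mutant) against L1 WT, where SASH3, PTPN7 and RASGRP3 did not (edgeR adjusted p = 0.227, 0.135 and 0.292). RNA of immune cells cannot be told apart from a change within the line. FCER1G, the highest marker listed in a mutant library, was at 0.302 TPM, and the 5 markers at 0 reads were listed in mutant replicate 1, but that library listed 1 of the 7 genes. In the others 3 markers were listed, NKG7 at 0 reads in replicate 2, which listed 6 of the genes, and LYZ and FCER1G at 2 and 3 reads in replicate 4, which are too few to decide. For the 4 genes listed in 2 or more mutant libraries, every mutant library lay above every other library that listed the gene. Those other libraries were few: L1 WT replicate 1 for JCHAIN and control replicate 3 for PRKCQ. For WIPF1 they were control replicate 2 and L1 WT replicate 3, and for SASH3 control replicate 1 and L1 WT replicate 3. The genes were picked for high values in the mutant, so this separation adds no support. No control listed JCHAIN or CD74, so higher in the mutant and lower in L1 WT cannot be told apart for them. Of the 4 genes, 2 or more still passed the threshold whichever mutant library was left out, though only 2 could be tested without replicate 2 or without replicate 4. Without replicate 2 these were JCHAIN against L1 WT and SASH3 against controls, and SASH3 did not pass against L1 WT. For these 4 genes, picked for their values, this argues against a single mutant library as the source. CD74, PTPN7 and RASGRP3 were listed in mutant replicate 2 and in no other mutant library, so without it 0 of these 3 could be tested and a single library stays open for them.

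In the median over pairs, the mutant libraries differed more from each other than the controls did. Over genes with at least 500 reads the ratio of their median differences was 1.39 (interval 1.25 to 1.56 over 1000 resamples of genes), above the bound of 1.2 set in advance, which argues against counting noise as the whole cause. The interval does not cover variation between libraries. Mutant replicates 1 and 2 (0.0557) and replicates 3 and 4 (0.0571) differed no more than pairs of controls (0.0451 to 0.0572). The excess lay between these 2 sets of mutant libraries (0.0675 to 0.101). What set these libraries apart was not tested, and no biological explanation was tested.

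Of 57 groups of 4 values examined, 5 had a value far from the other 3, where chance gives about 1 in 20. Besides the stress score these were the TMM factor of mutant replicate 2 (0.986), the G1/S score of mutant replicate 1 (-0.0919), the MYC and ribosome biogenesis score of control replicate 2 (0.0463) and the MAPK score of mutant replicate 3 (-0.12). The effects of the 2 reporter lines differed by a direct edgeR test for CLSTN2 (-5.005), CCL2 (-4.26), SYTL2 (-0.64), VSNL1 (0.45) and ETV1 (0.41), given as L1 WT minus mutant on the log2 scale. The BFP and hygromycin resistance sequence had 18 reads in control replicate 3 and was listed in no other library, and the labels do not say which cells carry it.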

How the results depend on the processing

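Fits by limma-trend, voom-type weights, TPM alone, at least 2 libraries per group, and the effect per library were chosen after seeing the data; the other alternatives were planned. Reading unlisted genes as 0 gave 0, 0 and 0 genes in the 3 comparisons, 0 lists against no reporter in either line and 0 shared genes; this counts missing values as absence. Under it 15 reported values that passed the threshold in the main fit reversed, and none passed after reversal. In L1 WT they were SLC20A1 -0.65, ABCC2 -0.66, SLC1A3 0.69, GPT2 0.60, PRPS2 0.69 and CXCL8 -0.21. In the mutant they were ABCC2 -0.53, VSNL1 -0.15, NUAK1 -1.17, SLC20A1 -0.72, HAX1 0.66, RPL11 0.66 and FXYD5 1.25. Between the lines they were ETV1 -0.59 and GRHL2 1.08. A fit to the 8 compared libraries gave 80 and 30 genes against no reporter. TPM alone gave 68 and, between the lines, 24; DESeq2 gave 8 between the lines; the cause was not tested. At least 2 libraries per group gave 7, 8 and 8 genes and 1 shared gene, with fewer genes tested. An absolute log2 fold change of at least 1 gave 3, 8 and 6 genes and 0 shared. Leaving out 1 library gave 7 to 34, 14 to 46 and 5 to 20 genes and 2 to 13 shared genes, partly because fewer genes could be tested. Splitting the controls gave 0 or 1 shared gene. The replicate block gave 91 genes for L1 WT and 15 shared genes; same-numbered libraries had residual correlations from -0.503 to 0.64, with 5 of 12 over 0.1 (controls with L1 WT: 0.640, 0.294, -0.0795 and 0.341) and a block correlation of 0.24, so the numbers were not taken to pair the samples. Of the reported genes' values under all alternatives 146 fell below the threshold in the same direction and 4 passed it. A further 1155 kept direction and side of the threshold, or passed in neither fit whatever their direction.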

Other observations

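The tests of exon sharing were set out before their results; the other values were chosen after the data were seen. Genes near the floor in controls had reads in a reporter line. The guanylate cyclase gene GUCY1A1 had 43 and 44 reads in L1 WT replicates 1 and 2 and 3 reads in control replicate 1, a ratio of 13.3 (95% exact counting interval 4.39 to 65.6). CLSTN2 had 126 and 144 reads in mutant replicates 1 and 2 and 3 reads in control replicate 4, a ratio of 37.3 (12.6 to 182). The chemokine gene CCL2 had 63 reads in mutant replicate 3 against 3 and 2 reads in control replicates 1 and 3, a ratio of 17.6 (7.14 to 56.0). These intervals cover counting error and not variation between libraries. The cadherin gene CDH2 had 2, 56 and 61 reads in mutant replicates 1, 3 and 4 and 0 reads in control replicate 2 and L1 WT replicate 2, with a log2 fold change that did not pass (edgeR adjusted p = 0.279).

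Interferon-stimulated genes scored 0.38, 0.02, 0.18 and 0.13 in the 4 L1 WT libraries and -0.18, -0.22, -0.24 and -0.03 in the 4 controls. Their effect per library was 0.30 (exact two-sided permutation p = 0.0571, adjusted p = 0.2 over 21 lists), so the list did not pass. The 4 mutant libraries scored 0.13, 0.05, -0.04 and -0.16, and over 3 members listed in both the mutant and the controls the effect per library was 0.36 (permutation p = 0.0571, adjusted p = 0.181 over 19 lists). Between mutant libraries, the median difference over genes with at least 500 reads was 0.0557 for replicates 1 and 2 and 0.0571 for replicates 3 and 4. It was 0.0957, 0.101, 0.0859 and 0.0675 for the other pairs, against 0.0451 to 0.0572 for pairs of controls.

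Some genes that proliferating cells use had few reads, such as ALDOA with 56 and 64 reads in control replicates 1 and 4 and NOP2 with 7 reads in control replicate 2. They share 42.3% and 54.4% of their exonic bases on the same strand, less than the genes tested below, so the test does not cover them. A hypothesis is that reads in exons shared with another gene were left uncounted. Of 321 protein-coding genes with at least 90% of exonic bases shared on the same strand, 320 had under 10 reads, against 36.5% of 8891 genes with under 1% shared, a ratio of 2.73. For 92 genes shared only with the opposite strand the ratio was 1.31 (Fisher's exact p = 0.0294), between the bounds set in advance, so whether counting ignored strand stays open. Such genes may be read too low here, and many of them may also be truly silent, which this test could not separate.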
